A study of Mus musculus with 13 samples.

How the data were processed

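RNA of sorted mouse thymocytes was hybridised to Affymetrix mouse gene ST arrays after whole-transcript labelling, per the labels' protocols, with 1 array per sample and 13 arrays. The deposited values are probe set intensities on a linear scale, summarised by the authors with RMA in Affymetrix Power Tools per the submitters' processing notes, which give no version here. RMA corrects background, normalises arrays to 1 distribution and summarises probes. The linear scale was read from the values, which ran from 6.16 to 23800. The log2 of each intensity was taken before testing, as the design foresaw for linear values. Array medians ran from 122.2 to 137.2 and upper quartiles differed, so array distributions were not identical. Arrays carry no read depth, and their number limits the precision.

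Of 24922 probe sets, 21425 had 1 gene symbol in the platform annotation, 1399 had several and 2098 were not listed there. Through the gene ID 21347 matched the RefSeq gene table, and 0 symbols changed. Only probe sets with 1 symbol were tested, and the brightest on average stood for each of the 921 genes with more than 1, which left 19752 genes. Probe sets for the Vγ2 chain name several genes and were not tested.

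Groups came from the sample titles: V2 WT, V2 cKO, DP WT and DP cKO. In the V2imm titles the knockout is written without the gene, and was read as the Sox4 conditional knockout of the series. Whether the 2 ways of writing V2 titles mark a batch is not stated. The fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend) had 4 group means and a covariate for the title set, over all arrays together so that small groups share 1 estimate of the spread. Comparisons were cKO against WT in V2 and in DP, the difference between these, and V2 WT against DP WT. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The 27 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a comparison. They covered thymocyte stages and lineages, T cell receptor signalling, miR-181, cell cycle, death, metabolism, stress, interferon response and markers of other cells, with 480 of 558 members measured.

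The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Sox4, up to 10 genes in each direction with the largest fold among called genes whose groups do not overlap, up to 5 with the smallest p in a direction where fewer than 10 passed, up to 4 genes with the smallest p from each list, and genes fixed in advance, leaving out sex-linked and receptor V segment genes. The fit without 2 arrays whose markers are those of the other population, and the use of the rule on that fit, were chosen after seeing the data. No array was moved to another group. Ranges over other normalisations, filters, moderation, blocks and left-out arrays are in the closing section.

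The fit was tested on simulated data with 200 changed genes among 19752. With 11 arrays it recovered 81% of genes changed by 1 log2 unit and 98% of those changed by 2 in V2, 52% and 92% in DP, and 67% and 94% between the populations. It made 11, 4 and 8 false calls. With 13 arrays the V2 shares were 81% and 100% and the DP shares 58% and 97%. Both runs took their means and spread from the 11-array fit, with independent noise. The simulated 13 arrays thus held no array with the other population's profile, so these shares do not describe the fit of the 13 arrays as labelled. Independent noise also leaves out differences of whole arrays, such as the low upper quartile of V2 cKO replicate 4 (V2imm). The shares for 11 arrays may therefore not hold for the real arrays. No genome sequence was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.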

Results

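Gene expression was measured in thymocytes sorted from 2-week-old mice, with 1 microarray per sample and 13 arrays in all. Both populations came from mice labelled wild type (WT) or conditional knockout (cKO) for Sox4, an HMG box transcription factor. V2 cells are immature γδ thymocytes that carry the Vγ2 chain of the γδ T cell receptor, sorted as high for the immaturity marker HSA and without CD4 and CD8. DP cells are the CD4 and CD8 double positive thymocytes of the αβ lineage. By label there were 4 V2 WT, 4 V2 cKO, 2 DP WT and 3 DP cKO arrays. The V2 titles are written in 2 ways, here called V2imm and immV2, with 2 WT and 2 cKO arrays each. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. In log2 intensity, DP WT replicate 3 had Xist, from the inactive X chromosome, at 5.59 and the Y chromosome gene Eif2s3y at 9.60. DP WT replicate 5 had 12.4 and 4.56, so their spread is not technical alone. V2 arrays labelled WT replicate 5 (V2imm and immV2) and cKO replicates 4 and 5 (V2imm) had Xist at 11.5 to 12.0. Their Eif2s3y was 8.61 to 8.96, so they carried markers of both sexes. The other V2 arrays had Xist at 5.36 to 6.08. Values were RMA intensities with array medians from 122.2 to 137.2, and the number of arrays limits the precision.

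Sox4 itself did not pass the threshold in either population. In V2 arrays its log2 intensity was 8.71, 8.64, 9.68 and 8.39 in those labelled WT, and 8.07, 9.60, 8.11 and 8.23 in those labelled cKO. So 3 of the 4 V2 cKO arrays were below every V2 WT array, and V2 cKO replicate 5 (V2imm) was not. In DP arrays it was 9.37 and 8.55 in WT, and 8.74, 8.68 and 8.94 in cKO. Over all 13 arrays the cKO minus WT difference was -0.35 (SE 0.36, adjusted p = 0.996) in V2 and -0.17 (SE 0.46, adjusted p = 1) in DP. In the 11 arrays kept below, Sox4 differed by -0.51 (SE 0.38) in V2 and -0.25 (SE 0.49) in DP. Within the title sets of V2 it differed by 0.16 (SE 0.42) in V2imm and -1.51 (SE 0.31, adjusted p = 0.25) in immV2, with 1 WT array. Sox4 had 1 probe set, and its place relative to the deleted part of the gene is not given in the sources used here, so this value may check nothing about the labels.

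Population markers placed 11 of the 13 arrays with their labelled population and 2 with the other one. The array labelled DP cKO replicate 5 had log2 intensities of 7.47 for Cd4, 7.65 for Cd8a and 6.87 for Rag1, a recombinase gene of αβ precursors. It read 11.5 for Sox13 and 12.0 for Etv5, transcription factors of γδ cells. The array labelled V2 WT replicate 5 (immV2) had 12.65 for Cd4, 12.94 for Cd8a and 13.02 for Rag1, with 7.73 for Sox13 and 6.60 for Etv5. All labels were kept. Each comparison is given for the 13 arrays as labelled and for the 11 arrays left without these 2, a choice made after seeing the data. The 11 arrays are 3 V2 WT, 4 V2 cKO, 2 DP WT and 2 DP cKO.

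**Figure D1:**
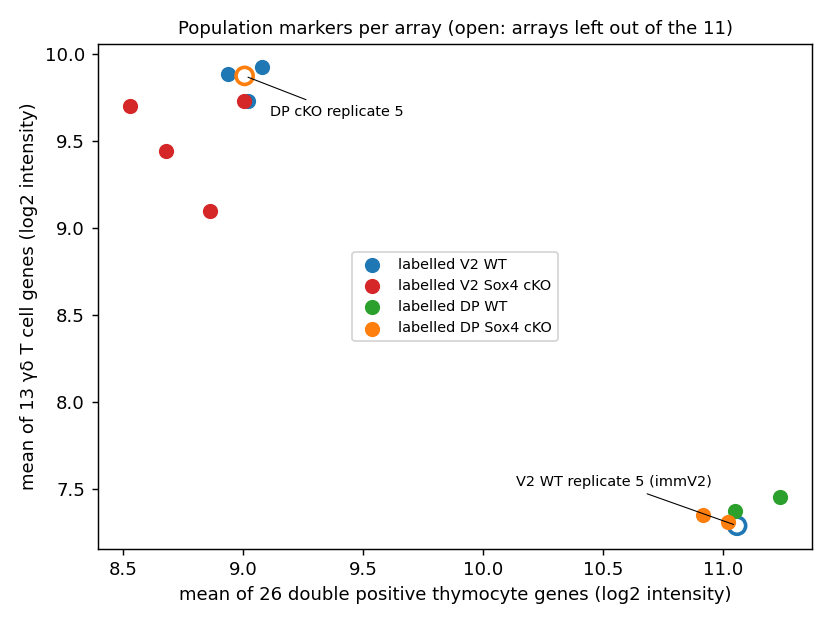
Mean log2 intensity of 26 double positive thymocyte genes (horizontal axis) against that of 13 γδ T cell genes (vertical axis), 1 point per array, coloured by labelled group, with the 2 arrays left out as open symbols. The array labelled DP cKO replicate 5 lies at 9.01 and 9.88, among the V2 arrays, and the array labelled V2 WT replicate 5 (immV2) at 11.1 and 7.29, among the DP arrays.

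V2 and DP wild-type cells were compared first, which shows what separates the populations. In the 11 arrays V2 WT cells (n = 3) were far higher than DP WT cells (n = 2) in Cpa3, a carboxypeptidase gene (log2 difference 7.30, SE 0.20). Its DP level of 4.97 ± 0.19 (SD, n = 2) lies below the lower quartile of every array, so the size of this difference depends on the background. They were also higher in Nkg7, a cytotoxic granule gene (5.48, SE 0.34), and in Etv5 (5.39, SE 0.23). In DP WT Nkg7 read 6.17 and Etv5 6.62, no higher than the granulocyte genes Mpo (6.80) and Cebpe (6.82), so levels this low are not shown to be above background and differences from them have no exact size. The V2 cells were lower in the recombinase genes Rag2 (log2 difference -6.15, SE 0.25) and Rag1 (-5.97, SE 0.18), and in the coreceptor genes Cd4 (-5.50, SE 0.18) and Cd8a (-5.14, SE 0.20). Rag2, at 5.30 in V2 WT, has the same limit as Cpa3. With limma, 962 of 19752 genes differed, 633 higher and 329 lower in V2. This count depended on single arrays, with 606 without V2 WT replicate 4 (V2imm) and 1575 without V2 cKO replicate 4 (V2imm). With the 13 arrays as labelled, 11 genes differed, 5 higher and 6 lower. That count was 2 without V2 WT replicate 4 (V2imm) and 141 without the array labelled V2 WT replicate 5 (immV2).

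The lists fixed beforehand followed these genes. Of 26 double positive thymocyte genes, 19 were lower and 1 was higher in V2 over all genes, and 21 and 1 adjusted over the list alone; Slc7a11, a cystine transporter gene, was lower (log2 difference -5.35, SE 0.15, adjusted p = 2.9e-10). Of 21 genes of the IL-17 γδ programme, 12 were higher over all genes and 14 adjusted over the list alone, among them Maf (log2 difference 4.87, SE 0.31), the Src-family kinase gene Blk (4.86, SE 0.39), Sox13 (3.36, SE 0.28) and Rora (2.50, SE 0.29). Of 21 type 1 lymphocyte genes, 9 were higher over all genes and 12 adjusted over the list alone, including Gzma, which encodes granzyme A (3.81, SE 0.23), and the cytokine receptor gene Il2rb (3.49, SE 0.26). Of 20 maturation and egress genes, 12 were higher over all genes and 13 adjusted over the list alone, including Gimap4 (4.10, SE 0.19), the interleukin-7 receptor gene Il7r (3.97, SE 0.23) and the egress receptor gene S1pr1 (3.19, SE 0.33). Of 13 γδ T cell genes, 9 were higher and 1 was lower by both counts, and of 12 NK and innate lymphoid markers 5 were higher by both counts, such as Cd7 (3.68, SE 0.22) and Gata3 (1.76, SE 0.23).

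Camera called 16 of the 27 lists in this comparison, and 6 held with an estimated correlation. Those 6 were the type 1 list (adjusted p = 0.00368 with an estimated correlation), the DP list (0.00709), the IL-17 and γδ lists (0.0095 each), and the maturation and NK lists (0.0352 each). Interferon-stimulated genes were called higher in V2 at a preset correlation, with 8 of 27 genes higher over all genes and 13 higher and 1 lower adjusted over the list alone, but adjusted p = 0.124 with an estimated correlation. Both measured genes of the miR-181 family that passed were lower in V2, Mir181a-1 (log2 difference -1.84, SE 0.28, adjusted p = 0.00128) and Mir181b-1 (-1.24, SE 0.29, adjusted p = 0.028). Among other genes named by the rule, Atp8b4 (4.89), Ccr8 (4.66), Igfbp4 (4.66), Slc15a1 (4.49) and Cd53 (4.45) were higher in V2 on the log2 scale, and Iftap (-6.06), Cd8b1 (-4.45), Nnat (-4.10), F13a1 (-4.09) and Ly6d (-3.93) were lower. Below the lower quartile of every array, where the size of a difference depends on the background, also lay Iftap (4.39), Slc7a11 (5.23) and Mir181a-1 (5.30) in V2 WT, and Atp8b4 (5.22) and Ccr8 (5.62) in DP WT. As labelled, Klk1b22 (log2 difference 3.02, SE 0.22), BC018473 (3.10, SE 0.27) and Gdpd3 (2.68, SE 0.33) were among the 11, but with the V2 arrays of the immV2 set alone in the 11, which has 1 WT array, they were -0.15, -0.38 and -0.20.

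In V2 cells, 6 of 21 measured genes of the IL-17 γδ programme were lower in arrays labelled cKO (n = 4) than in arrays labelled WT (n = 3) in the 11 arrays, adjusted over the list alone, and none passed over all genes. The transcription factor genes Sox13 and Maf differed by -1.04 (SE 0.23) and -1.14 (SE 0.26) on the log2 scale, Blk by -1.35 (SE 0.33) and Etv5 by -0.80 (SE 0.19). The receptor genes Il17re and Ccr6 differed by -1.08 (SE 0.16) and -0.94 (SE 0.25). The list as a whole did not pass with an estimated correlation (adjusted p = 0.194). Its median difference was -0.128, or -0.218 without V2 cKO replicate 4 (V2imm). For 98 other genes, chosen as high in the same V2 WT arrays, the median was -0.166, or 0.041 without that array. In the 11 arrays Btla, an inhibitory receptor gene of lymphocytes, was 2.75-fold higher in cKO (log2 difference 1.46, SE 0.19, adjusted p = 0.0572) without passing. As labelled, with the array labelled V2 WT replicate 5 (immV2) included, Sox13 (-0.09, SE 0.85), Maf (-0.03, SE 1.03), Blk (-0.13, SE 1.10) and Etv5 (0.49, SE 1.23) showed no difference above their errors.

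No gene passed the threshold in V2 with limma. In the 11 arrays 44 genes passed without V2 cKO replicate 5 (V2imm), 7 without V2 cKO replicate 4 (immV2) and 5 without V2 WT replicate 3 (immV2). A fixed replicate block, which pairs same-numbered arrays of a title set, gave 34, though replicate numbers were not taken as pairs. There were 794 of 19752 genes at an unadjusted p below 0.05 with 13 arrays and 757 with 11, and the smallest adjusted p was 0.234 and 0.0572. Of the genes with the smallest p in the 11 arrays, Itga2, a collagen-binding integrin gene (log2 difference 0.79, SE 0.12), Abcb1b, an efflux pump gene (0.90, SE 0.14), Cysltr1, a leukotriene receptor gene (1.13, SE 0.18), and the adhesion gene Cd2 (1.01, SE 0.16) had higher values in cKO. Slc7a8, an amino acid transporter gene (-1.88, SE 0.28), 1700048O20Rik (-1.25, SE 0.18), the interferon-γ receptor gene Ifngr1 (-1.27, SE 0.20) and Tmtc2 (-0.72, SE 0.12) had lower values. Their adjusted p ran from 0.0572 to 0.0702. As labelled, the rule also named Gpr174 (1.33, SE 0.23), Pla2g4a (0.63, SE 0.11), Slc35d1 (-1.15, SE 0.19), Plcl1 (-0.80, SE 0.14) and Cass4 (-0.56, SE 0.12), none called.

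The V2 lists were tested in the 11 arrays. The IL-17 list was called lower by camera (15 of 21 genes lower, median log2 difference -0.13, adjusted p = 2.7e-06), with adjusted p = 0.194 with an estimated correlation. HMG box factors other than Sox4 (adjusted p = 1.2e-04) and γδ T cell genes (1.2e-04) were also called lower, with adjusted p = 0.194 and 0.248 with an estimated correlation. No gene of either passed over all genes; adjusted over the list alone, Sox13, Tox3 (-0.70, SE 0.18) and Sox5 (-0.52, SE 0.16) fell among 20 HMG box genes, and Sox13, Etv5, Blk and Slamf1 (-0.68, SE 0.20) among 13 γδ genes. The DP thymocyte list was called lower (6.7e-04), with adjusted p = 0.476 with an estimated correlation; adjusted over the list alone Plxnd1 (-1.22, SE 0.25) and Slamf1 fell and Cd8b1 (0.63, SE 0.19) rose, with 0 of 26 over all genes. The invariant NKT list was called lower (0.00619), with adjusted p = 0.194 with an estimated correlation; over the list alone the vitamin D receptor gene Vdr (-1.61, SE 0.29) and Slamf1 fell and Il17rb (0.96, SE 0.29) rose, with 0 of 23 over all genes.

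Interferon-stimulated genes were called higher in V2 cKO, with 23 of 27 genes above WT (median log2 difference 0.24, adjusted p = 4.6e-05) but adjusted p = 0.595 with an estimated correlation. No gene of this list passed by either count. Ifit3 (0.77, SE 0.28) and Ifit1 (0.64, SE 0.22) were above WT and Usp18 (-0.54, SE 0.24) below. Within V2imm Ifit3 differed by 0.22 and Ifit1 by 0.40, against 1.59 and 0.99 within immV2, which has 1 WT array. Maturation and egress genes were called higher (0.00424), with adjusted p = 0.642 with an estimated correlation. Adjusted over the list alone Ms4a4b (0.73, SE 0.17) and Il6ra (1.07, SE 0.28) rose, with 0 of 20 over all genes. The list holds Cd24a, the gene of the sort marker HSA. Its log2 intensity was 12.2, 12.0 and 11.7 in V2 WT. In V2 cKO it was 12.3 and 11.6 in V2imm, and 10.4 and 9.46 in immV2. In DP it averaged 12.1 in WT and 10.9 in cKO. Whether the sorted groups differed in maturity was not tested. Macrophage and dendritic cell markers had 19 of 22 genes above WT (adjusted p = 0.0684). In the 4 V2imm arrays Cd74 was 10.2, 9.93, 8.19 and 10.98 on the log2 scale, against 6.19, 7.77 and 6.48 in the 3 immV2 arrays. The lists for proximal, negative and early induced genes of receptor signalling, miR-181, type 1 lymphocytes, single positive and double negative stages, cell cycle, apoptosis, Wnt targets, glycolysis, cholesterol synthesis, stress, sex-linked genes, and B, granulocyte, erythroid, stromal and NK markers were not called (adjusted p from 0.0548 to 0.895). Single genes passed over their list alone: Mmp9 (-0.69, SE 0.12) among granulocyte markers, Ctla4 (0.48, SE 0.12), Id2 (0.81, SE 0.22) and Cd2.

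Within the title sets, the IL-17 list had a median difference of -0.23 in the V2imm arrays, with 17 of 21 genes lower, and of -0.07 in the immV2 arrays, with 13 of 21 genes lower and 1 WT array against 2 cKO arrays. There were 12 genes lower in both sets. Sox13 differed by -1.39 (SE 0.27) in V2imm and -0.50 (SE 0.27) in immV2, Maf by -1.11 (SE 0.31) and -1.19 (SE 0.38), Il17re by -0.88 (SE 0.20) and -1.38 (SE 0.21), and Btla by 1.69 (SE 0.22) and 1.12 (SE 0.25). V2 cKO replicate 4 (V2imm), with the lowest Blk (8.74) and Sox13 (9.38) of the V2 arrays that are among the 11, also had the lowest upper-quartile intensity of all arrays, 332.7. With 13 arrays as labelled camera called 8 lists, of which 0 held with an estimated correlation, and the IL-17 list was not among them.

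**Figure D2:**
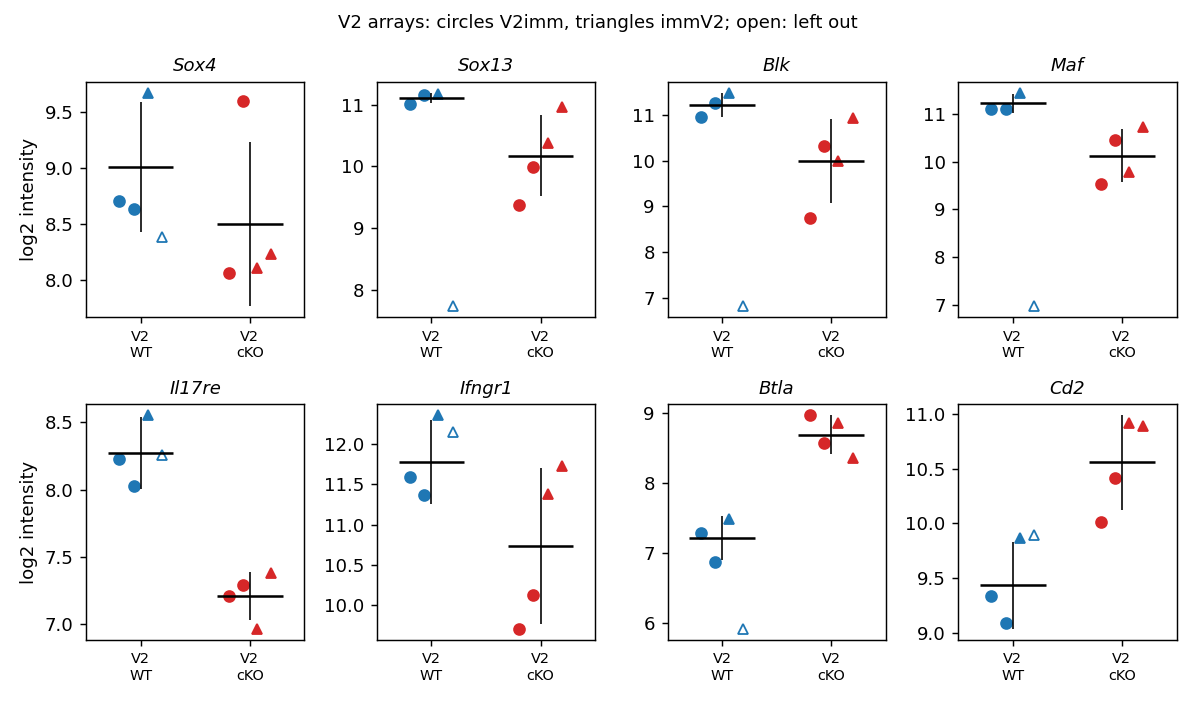
Log2 intensity of 8 genes in the V2 arrays labelled WT (blue) and cKO (red), 1 symbol per array, circles for V2imm and triangles for immV2 titles. Lines are the mean ± SD of the arrays kept among the 11 (n = 3 WT and 4 cKO), and the open triangle is the array labelled V2 WT replicate 5 (immV2); Sox13 averaged 11.1 in WT and 10.2 in cKO, and Btla 7.21 and 8.68.

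In DP cells 5 genes differed between arrays labelled cKO and WT in the 11 arrays (n = 2 each). Nnat, which encodes neuronatin, fell by 3.88 on the log2 scale (SE 0.42, adjusted p = 0.0075), from 11.2 ± 0.43 (SD, n = 2) in WT to 7.33 ± 0.98 (SD, n = 2) in cKO. B3gnt5, a glycosphingolipid synthesis gene, fell by 2.00 (SE 0.24, adjusted p = 0.0075). Cd53, a tetraspanin gene of leukocytes, rose 4.84-fold (log2 difference 2.28, SE 0.26, adjusted p = 0.0075). Ero1b, an oxidase gene of the endoplasmic reticulum, rose by 2.06 (SE 0.24, adjusted p = 0.0075), and Slc28a2b, of a nucleoside transporter family, rose 3.80-fold (1.92, SE 0.24, adjusted p = 0.00885).

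With the 13 arrays as labelled no gene passed with limma (409 at an unadjusted p below 0.05, smallest adjusted p = 0.506). In that fit Nnat was -3.46 (SE 0.58), Cd53 3.03 (SE 0.76), Ero1b 1.51 (SE 0.54), B3gnt5 -1.37 (SE 0.56) and Slc28a2b 0.80 (SE 0.86). The 5 calls in the 11 arrays fell to 0 in a fit of the DP arrays alone, and to 0 with a covariate that coded Xist as on or off. Among these DP arrays that code marked only DP WT replicate 5. The calls also did not hold without DP WT replicate 5, which leaves 1 DP WT array. The differences kept their direction over 24 settings, from -4.58 to -2.88 for Nnat, 2.03 to 3.03 for Cd53, 1.51 to 2.52 for Ero1b, -2.12 to -1.37 for B3gnt5 and 0.80 to 2.25 for Slc28a2b. Xist, expressed from the inactive X chromosome, was 12.4 in DP WT replicate 5 and 5.59, 5.52 and 5.61 in the other DP arrays of the 11, while the labels give the sex as mixed.

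Among genes that did not pass in DP, Tax1bp3, which encodes a PDZ domain protein, was -2.40 (SE 0.36, adjusted p = 0.0527), Smoc1 -1.14 (SE 0.18), and the carbonic anhydrase gene Car2 -1.18 (SE 0.20) on the log2 scale. Car3, which muscle expresses, was at 0.97 (SE 0.15), and 22 of 24 other skeletal muscle transcripts were also higher in these cKO arrays on average, mainly in DP cKO replicate 3. Cyth4 was 2.63-fold above WT (adjusted p = 0.0709). As labelled the rule also named Rab37 (1.31, SE 0.21), Sting1 (2.20, SE 0.48), Slc16a6 (0.88, SE 0.20), D6Ertd474e (-0.63, SE 0.11), Tiparp (-0.97, SE 0.24) and B330016D10Rik (-0.79, SE 0.19). Of the 6 measured miR-181 genes none passed by either count, with Mir181a-1 at 0.56 (SE 0.30), Mir181b-1 at 0.55 (SE 0.32) and Mir181b-2 at -1.27 (SE 0.51). The signalling phosphatase genes Ptpn22 (0.17, SE 0.28) and Ptpn11 (-0.03, SE 0.22) differed by less than their errors, as did Cd4 (0.11, SE 0.20), Cd8a (0.01, SE 0.22) and Rag1 (0.04, SE 0.20).

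Camera called 1 list in DP, the double positive thymocyte genes, with 13 of 26 genes higher and 13 lower (median log2 difference -0.02, mean -0.18, adjusted p = 0.0175) and adjusted p = 0.815 with an estimated correlation. Slc7a11 (-0.85, SE 0.16) fell adjusted over the list alone and no gene of it over all genes. Of the single positive lineage list, not called, Ctla4 (0.55, SE 0.15), Runx3 (1.01, SE 0.28) and Nrp1 (0.68, SE 0.24) rose and Icos (-1.11, SE 0.39) fell adjusted over the list alone, with 0 of 15 over all genes. Myc (0.91, SE 0.22) rose over its list alone among 26 genes induced early by receptor signalling. The IL-17 list had 11 of 21 genes lower (median -0.06, mean 0.04, adjusted p = 0.885). As labelled camera called 9 lists, with 0 called with an estimated correlation.

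**Figure D3:**
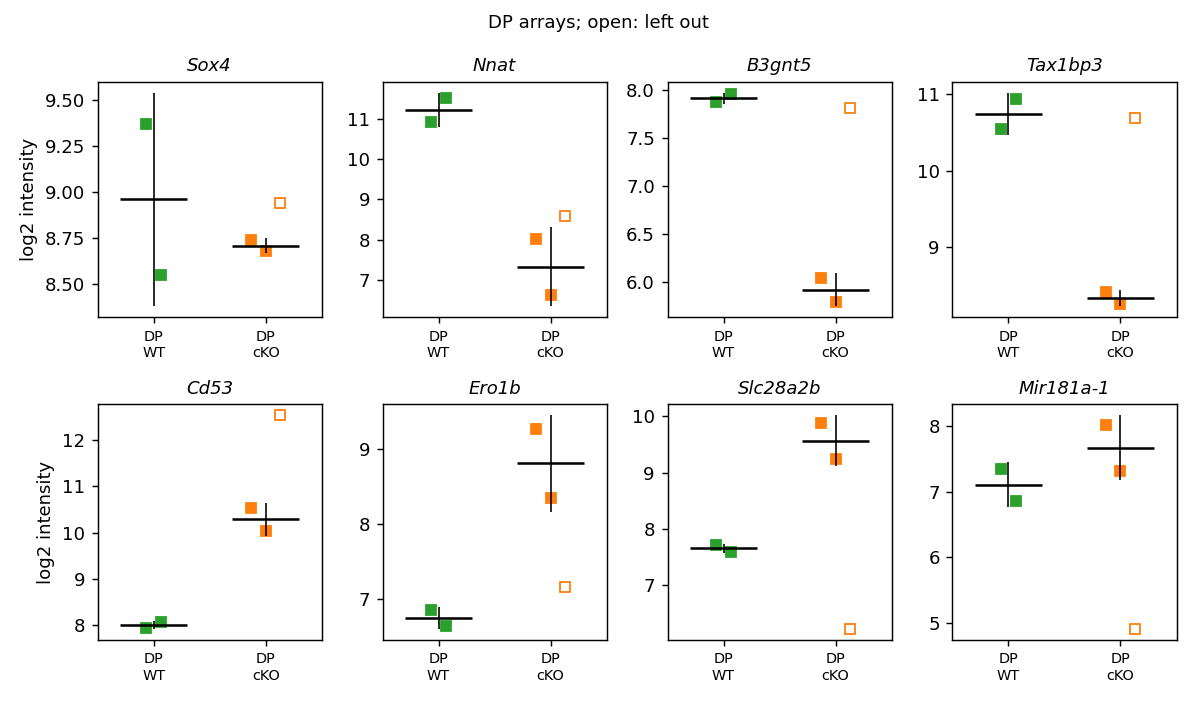
Log2 intensity of 8 genes in the DP arrays labelled WT (green) and cKO (orange), 1 square per array; lines are the mean ± SD of the arrays kept among the 11 (n = 2 each), and the open square is the array labelled DP cKO replicate 5. Nnat averaged 11.2 in WT and 7.33 in cKO, and Cd53 8.01 and 10.3.

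The genotype difference was compared between V2 and DP cells by an interaction term. Of the IL-17 list, Maf (-1.86, SE 0.42), Il17re (-0.98, SE 0.26), Sox13 (-1.21, SE 0.38) and Blk (-1.69, SE 0.53) were more negative in V2 than in DP adjusted over the list alone in the 11 arrays, with 0 of 21 over all genes. In DP WT Maf was 6.39, Blk 6.49 and Sox13 7.85, against 11.2, 11.2 and 11.1 in V2 WT, so these 3 had less room to fall in DP and their values do not show that DP cells respond less. The list as a whole was called (median -0.17, adjusted p = 3.9e-04), with adjusted p = 0.712 with an estimated correlation. Cd53 (-2.39, SE 0.33), Ero1b (-2.07, SE 0.31), Nnat (3.24, SE 0.53), Tmsb10 (2.04, SE 0.34) and Smoc1 (1.33, SE 0.23) had the smallest p among named genes and did not pass (adjusted p from 0.146 to 0.233). No gene passed with limma in either set, with 305 genes at an unadjusted p below 0.05 with 13 arrays and 372 with 11. As labelled camera called 0 lists.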

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

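The tests of the exchanged arrays, and the test without 1 V2 array, were chosen after their results were seen; the tests of dilution, of chance splits, of muscle transcripts and of the neighbours of Sox4 were set before theirs. All use the 11 arrays unless said otherwise.

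The array labelled V2 WT replicate 5 (immV2) stood apart in its group of 4 as labelled. Among 271 named genes it was the lone array in 45, and its correlation with its own group was 0.966. Its mean log2 intensity was 11.1 over DP genes, 7.29 over γδ genes and 6.69 over the IL-17 list. Lone values are met by chance in about 1 in 20 groups. The named genes include those with the largest V2 against DP differences in the fit without this array. An array with a DP profile stands apart on such genes, so the 45 are no separate evidence of its identity. Other arrays were lone in fewer named genes: 5 for V2 cKO replicate 4 (immV2), 9 for V2 cKO replicate 4 (V2imm), 4 for V2 cKO replicate 5 (V2imm), 3 for V2 WT replicate 3 (immV2) and 5 for V2 WT replicate 5 (V2imm).

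A mixture of both populations in the sorted samples was tested on 100 genes that separate them. The labelled population contributed at most 0.336% of their signal in both arrays, against the 10% a mixture was set to need, which argues against it. An exchange of the samples stays open. On 50 genes that separate V2 genotypes in the other arrays (0 the WT mean, 1 the cKO mean) the array labelled DP cKO replicate 5 scored -0.036, below every held-out V2 cKO array (0.354 to 1.10) and near held-out V2 WT arrays (0.013 to 0.326). On genes that separate DP genotypes the array labelled V2 WT replicate 5 (immV2) scored 0.793, but held-out DP WT arrays (0.426 and 0.567) and DP cKO arrays (0.535 and 0.744) overlap, so this part may say little; its B3gnt5 was 6.09, Ero1b 9.05, Slc28a2b 9.25, Cd53 10.1 and Nnat 9.13 on the log2 scale, against means of 7.91, 6.75, 7.64, 8.01 and 11.2 in DP WT and 5.92, 8.81, 9.57, 10.3 and 7.33 in DP cKO. Its Nnat thus lay between the 2 groups.

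The IL-17 list was lower in V2 cKO than WT, and its difference between V2 and DP was called, with a median of -0.175, but with an estimated correlation adjusted p = 0.194 in V2 and 0.712 for the difference. Without V2 cKO replicate 4 (V2imm) the list's median was -0.218 (bootstrap interval over genes -0.283 to -0.005), so the lower median did not rest on that array alone. The interval treats the genes as independent and holds no spread between arrays, so it does not test whether the remaining arrays differ. A lower share of γδ cells in the cKO samples stays open. Probe set 10403821, which names the Vγ2 chain among other genes, read 14.072, 13.885, 13.867 and 13.87 in V2 cKO on the log2 scale. It read 13.997, 14.06 and 13.997 in V2 WT, and 8.726 and 9.082 in DP WT. The first V2 cKO value, of replicate 4 (V2imm), was above every V2 WT array, and the others were below. These values point both ways. Whether so bright a probe set follows a small change in cell share was not tested. The 98 other genes that are high in V2 cells had a median of -0.166 (-0.279 to -0.080), inside the list's interval of -0.578 to -0.040. They were chosen as high in the same V2 WT arrays, which can lower this median without any change in cell share, so it cannot decide. Without V2 cKO replicate 4 (V2imm) it was 0.041. On the 100 genes that separate the populations that array had 20.8% of the DP signal, against 0.27%, 0.02% and -1.38% in the other V2 cKO arrays, but its Rag1 of 6.93 and Cd4 of 6.84 were at the V2 WT means of 7.02 and 6.86. Chance cannot be excluded: the median was -0.128 in the real split, 7 of 34 splits of the 7 V2 arrays gave one as low, and the lowest other was -0.477. A change in the cells by loss of Sox4 is a hypothesis that these tests leave open.

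Chance splits of V2 arrays were also counted for the numbers of genes. For genes at an unadjusted p below 0.05 chance cannot be excluded: 18 of 34 splits gave at least the 794 as labelled (highest other 3484), and 19 of 34 at least the 757 with 11 arrays (highest other 6553). With 0 genes called every split gives at least as many, 34 of 34 as labelled (highest other 0) and 34 of 34 with 11 arrays (highest other 3410), so these 2 counts say nothing about chance. The split with 3410 genes put the 3 immV2 arrays with V2 cKO replicate 4 (V2imm). The splits that put them with V2 WT replicate 4, V2 WT replicate 5 or V2 cKO replicate 5 of V2imm called 0, 0 and 1. Every split was fitted with the title covariate, so such splits in effect set 1 V2imm array against the rest of V2imm. They could not point to the titles, and show only that the high count came with V2 cKO replicate 4 (V2imm).

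V2 cKO replicate 4 (V2imm) had an upper quartile of 332.7 and a 99th percentile of 5214 in intensity, and a correlation of 0.958 with its group, each apart from the other 3 V2 cKO arrays. Probe set 10345675, outside the genes tested because no gene is listed for it, differed by -1.55 (SE 0.147, adjusted p = 0.00704 over the left-out probe sets) between V2 cKO and WT, and was 7.57 and 7.81 in DP WT against 6.34 and 6.01 in DP cKO. It was 6.08 in the array labelled V2 WT replicate 5 (immV2) and 8.89 in the array labelled DP cKO replicate 5, where the 3 V2 WT arrays of the 11 had 7.81, 7.41 and 7.30 and the V2 cKO arrays 5.66 to 6.15.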

How the results depend on the processing

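Settings on the 11 arrays, the Xist covariate and the rule that a reversal needs both values above their SE were chosen after seeing the data; the cause of each move was not tested. Numbers are genes called unless said otherwise. Leaving out the 2 doubted arrays moved DP from 0 to 5 and V2 against DP wild type from 11 to 962.

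As labelled, V2 cKO against WT gave 0 and moved to 2 with quantile normalisation, 10 with array weights and 1 in each title set alone; V2 against DP wild type moved from 11 to 0 without the title covariate, 6 with its own groups, 20 with quantile normalisation, 127 with array weights, 65 in V2imm and 0 in immV2. With 11 arrays V2 moved from 0 to 1 and 9 with the filters on mean and highest group mean, 11 with quantile normalisation, 6 with robust moderation, 2680 with array weights and 6 in V2imm alone; the weights did not converge and gave V2 WT replicate 3 (immV2) 36.3. DP moved from 5 to 3 without the covariate, 0 with its own groups, 9 with quantile normalisation, 29 with array weights and 0 with the Xist covariate. The difference between V2 and DP moved from 0 to 1 with quantile normalisation and 48 with array weights, and V2 against DP wild type from 962 to 594 without the covariate and 2320 with array weights.

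Replicate numbers were not taken as pairs, because 1 pair of same-numbered arrays, V2imm replicate 5, correlated at -0.063 with 13 arrays and -0.108 with 11. The other 4 pairs were at 0.306 to 0.424 and the other 3 at 0.179 to 0.524. Each pair was a WT and a cKO array of 1 title set. Deviations from group means were correlated, which keep any title set difference, and 1 pair of the 13 arrays held the array labelled DP cKO replicate 5. V2 and DP arrays of the same number and genotype were not compared, so a pairing between the populations was not tested. A fixed replicate block gave, with 13 arrays, 3 in DP and 2 for the difference, and with 11 arrays 34 in V2, 8 in DP and 4 for the difference; V2 against DP wild type could not be fitted with it.

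Leaving out 1 array at a time gave, with 13 arrays, 0 in V2, DP and their difference and 2 to 141 between the populations. With 11 arrays it gave 0 to 44 in V2, 0 to 14 in DP, 0 to 4 for the difference and 477 to 1575 between the populations; 44 came without V2 cKO replicate 5 (V2imm), and 0 in DP without DP WT replicate 5.

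Camera called 8, 9, 0 and 10 lists in V2, DP, their difference and V2 against DP wild type as labelled, and 0 with an estimated correlation or fry. With 11 arrays it called 7, 1, 1 and 16, and with an estimated correlation 0, 0, 0 and 6, with fry 0 in the first 3. Without the covariate DP had 0 and the difference 2, and without V2 cKO replicate 4 (V2imm) V2 had 12 and the difference 6.

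There were 12780 values of named genes over the settings. Of these, 12311 stayed on their side of the threshold without a reversal, 278 newly passed, 185 no longer passed and 6 reversed. Changes of sign with either value below its SE did not count as reversals, so the 12311 can include changes of direction. Mir181b-2 reversed to 0.49 in V2 with V2imm arrays alone and without V2 WT replicate 3 (immV2), ranging from -0.89 to 0.49 over left-out arrays, and its difference to -0.52 in immV2; BC018473 (-0.38), Gdpd3 (-0.20) and Klk1b22 (-0.15) reversed between the populations in immV2 with 11 arrays.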

Other observations

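The muscle list was written after 5 muscle genes were seen to be high and before its own values were seen, and the tests here use the 11 arrays.

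Skeletal muscle transcripts were on average higher in the DP arrays labelled cKO than in those labelled WT, most of all in DP cKO replicate 3, without any passing the threshold over all genes. Myl1, a myosin light chain gene, had 10.6 and 9.73 on the log2 scale in cKO against 9.01 and 6.79 in WT (difference 2.26, SE 0.52, adjusted p = 0.424). The titin gene Ttn had 7.26 and 6.81 against 6.44 and 6.22, and the nebulin gene Neb 7.63 and 6.97 against 6.47 and 6.36. The array labelled V2 WT replicate 5 (immV2), with DP markers, had 6.57 for Myl1. Of 24 other muscle transcripts, 22 were higher in cKO, with a median difference of 0.378 (bootstrap interval 0.215 to 0.770), above all 10000 random lists of matched level. The interval and the random lists treat genes as independent and hold no spread between arrays. Transcripts that rise together in 1 sample would give the same outcome, so it does not show a difference by genotype. DP cKO replicate 3 was above both WT arrays in 23 of the 24 and DP cKO replicate 4 in 13, and without replicate 3 the median was 0.189. DP WT replicate 3 also had more than DP WT replicate 5 of the creatine kinase gene Ckm (8.46 against 7.48) and the calcium pump gene Atp2a1 (8.05 against 7.02), so the level differs between single samples as well as by label. Skeletal muscle RNA in the DP cKO samples, chiefly in replicate 3, or muscle-like cells of the thymus carried through the sort, is a possible explanation, and the sort on CD4 and CD8 should remove such cells. No biological explanation was tested.

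Sequence from another strain around Sox4 was tested as a source of the DP differences. Of the 100 measured neighbours of Sox4, 1% had an unadjusted p below 0.01 against 0.799% of other genes (one-sided Fisher's exact test, p = 0.553), with 1 neighbour, H2bc4, at that level. A single gene is too few to decide.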
